A study of Homo sapiens with 22 samples.

How the data were processed

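Gene expression was measured by RNA sequencing in snap-frozen human peripancreatic adipose tissue, the fat that surrounds the pancreas. The 22 libraries came from 4 groups: 5 controls (CTRL), 7 with chronic pancreatitis (CP), 5 labelled as resolved pancreatitis (HP) and 5 from donors with type 2 diabetes (T2D). Per the labels' protocols, RNA was extracted with a lipid tissue kit after mechanical dissociation and the libraries were sequenced on an Illumina HiSeq instrument. Per the submitters' processing notes and the series' design text, reads were aligned to hg38 with HISAT2 2.2.1 and counted per gene with featureCounts 2.0.6, and DESeq2 was the submitters' tool for comparing groups, with genes of low total count left out. Whether counting used the strand of the reads, how reads with several alignments were treated and which annotation was used are not given in the sources used here.

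The deposited table holds 58735 genes in the unit FPKM, 1 column per library, together with each gene's length. How the authors turned counts into FPKM is not stated. Multiplying a deposited FPKM value by the gene's length gave whole multiples of 1 step in each library, within a tolerance of 0.05 reads for 100% of values above 0, so the number of reads behind each value could be recovered. The recovered totals were 48.2 to 66.7 M reads per library. The totals divided by the authors' own FPKM denominator ranged from 0.841 to 1.19, so that denominator was not the sum of the reads listed. Depth was therefore similar in all libraries, and a gene of 1 kb with 3 reads would have had an FPKM of 0.0397 to 0.0615.

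For the tests, each library's FPKM was divided by its median-of-ratios factor, which lay between 0.996 and 1.005. Genes with an FPKM of at least 1 in at least 5 libraries were kept, which left 15502 genes. The values were analysed as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, in a single fit of all 4 groups with a mean-variance trend and robust moderation. Fold changes are on that log2(FPKM + 1) scale, which understates the change of genes of low expression. A gene was called changed at an adjusted p under 0.05 (two-sided, Benjamini-Hochberg over the 15502 genes of a comparison). A log2 change given for a gene is an estimate, and the gene was not called unless that is said. The 4 main comparisons were CP, HP and T2D against controls and CP against HP, and 3 secondary comparisons and a test of any difference among the 4 groups were summarised. The p-values measure the spread between the samples of a group.

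A total of 46 gene lists for cell types, pathways and RNA quality were written before the data were examined, and 43 of them had at least 5 members among the genes kept. These were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 43 lists of a comparison. Camera was repeated with a correlation estimated from the data, and fry, which asks whether a list's genes move on balance one way, was run on the same lists. For each list and library a score was also computed as the mean of log2(FPKM + 1) over the members, and group differences were tested with exact two-sided permutation tests, adjusted over 184 tests. With so few libraries, a list whose score separates the groups fully can still miss the threshold after that adjustment. The scores of cell type lists were planned, and those of the pathway and quality lists were added after seeing the data.

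The groups, comparisons, tests, lists and the rule for naming genes were fixed before the data were examined. The rule named the 10 protein-coding genes with the smallest p in a comparison when fewer than 10 genes passed the threshold, the 2 to 4 members with the smallest p of each list described, and 12 background genes of adipose, immune and pancreatic cells. Genes named outside that rule are said to be so. Not every gene that the rule selects is named in the text. Y-linked genes and XIST were not named. The submitters' own DESeq2 results were not used here.

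The analysis was tested on simulated data in which 100 genes each were changed by 1 and by 2 on the log2 scale in the 15502 genes kept. In the simulated comparison of CP with controls, 64% and 86% of them were called, with 9 false calls. The shares were 49% and 85% for HP against controls with 10 false calls, 53% and 91% for T2D against controls with 6, and 64% and 91% for CP against HP with 6. The simulated noise was normal and independent between genes, and all the changed genes were present together. Libraries that stand apart and genes that vary together were not simulated, so these shares need not hold for the real data.

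Alternatives covered the scaling, the pseudocount, the filter on low values, the biotypes, the fit, library weights, the score of pancreatic acinar genes as a covariate, the replicate number as a block, the thresholds, the list test and each library left out in turn. Limma-voom on the recovered reads, a filter of at least 100 recovered reads, and leaving out CP 2, HP 5, T2D 1 and CTRL 5 together were added after seeing the data. So were the tests of the mitochondrial share with 1 library left out, the scores without CP 2 or HP 5, and the choice to describe first the lists that kept their call without any 1 library. A call kept that way still rests on the preset correlation between genes, and does not test it. The recovered reads were fitted with limma-voom, and negative binomial count models were not run.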

Results

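Peripancreatic adipose tissue from 22 samples was profiled by RNA sequencing, in 5 controls, 7 samples with chronic pancreatitis (CP), 5 labelled as resolved pancreatitis (HP) and 5 from donors with type 2 diabetes (T2D). The deposited FPKM corresponded to 59.95 ± 1.75 M reads per library in controls (SD, n = 5), 58.2 ± 5.47 M in CP (n = 7), 56.5 ± 4.30 M in HP (n = 5) and 56.5 ± 6.56 M in T2D (n = 5). The number of reads did not differ beyond the spread between libraries in any of the 4 main comparisons (exact permutation p = 0.143 to 0.563, adjusted p = 0.190 to 0.563 over 12 tests of depth and composition). At least 1 read was found for 25202 to 29857 genes per library.

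The tissue pieces carried the transcripts of fat cells, stroma and immune cells. ADIPOQ, which encodes adiponectin, had an FPKM of 346 ± 260 in controls (SD, n = 5), 252 ± 243 in CP (n = 7), 170 ± 122 in HP (n = 5) and 286 ± 93.7 in T2D (n = 5). PLIN1, a coat protein of lipid droplets, stood at 445 ± 281, 260 ± 199, 319 ± 280 and 425 ± 96.4, and LEP, which encodes leptin, at 137 ± 154, 86.9 ± 76.7, 66.7 ± 40.4 and 181 ± 129, in the same order. Pancreatic transcripts were scarce. INS had at most 2 reads in any library, the trypsinogen gene PRSS1 (which shares sequence with close paralogs and is uncertain) at most 0.854 FPKM and the carboxypeptidase gene CPA1 at most 1.73 FPKM. The score of the pancreatic acinar list, the mean of log2(FPKM + 1) over its members, was 0.36 ± 0.11 in controls and 0.25 ± 0.07 in CP, a difference of -0.10 with an exact permutation p of 0.0682 (adjusted p = 0.697), and it differed by -0.08 in HP (exact p = 0.302) and by -0.10 in T2D (exact p = 0.103). KRT19, a keratin of ductal and mesothelial cells, varied widely within groups, with 15.8 ± 31.8 FPKM in T2D and 7.91 ± 16.2 in CP against 3.24 ± 4.50 in controls and 1.17 ± 2.12 in HP. CD68, a common macrophage marker, is uncertain here because 81.6% of its exon bases lie in exons of an overlapping gene on the same strand (ENSG00000264772), and it stood between 0.0304 and 0.348 FPKM.

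Samples of a group were no closer to each other than to samples of other groups. The median correlation of log2(FPKM + 1) across genes was 0.900 between libraries of a group and 0.901 between libraries of different groups. Differences between the 4 groups held 12.99% of the variance, against 14.3% given by chance. The first principal component held 19.9% of the variance.

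Chronic pancreatitis was compared with controls to see how the fat depot differs in that disease. In CP, the share of reads from the mitochondrial genome was lower than in controls. Extracellular matrix and macrophage genes were higher as lists at the preset correlation between genes only, with an adjusted p of 0.113 and 0.330 with an estimated correlation. Reads from the mitochondrial genome made up 12.3 ± 3.16% of reads in CP (SD, n = 7) and 25.1 ± 5.04% in controls (n = 5), with 7 of 7 CP libraries below the lowest control (exact permutation p = 0.00126, the smallest the design can give, adjusted p = 0.00758 over 12 tests). The 24 matrix genes had a median log2 change of 0.97, and the matrix score was higher in CP by 0.86, with 6 of 7 CP libraries above the highest control (exact permutation p = 0.00884, adjusted p = 0.417 over 184 score tests). The 15 macrophage genes had a median log2 change of 0.80. The 20 adipocyte genes had a median of -0.76.

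**Figure D1:**
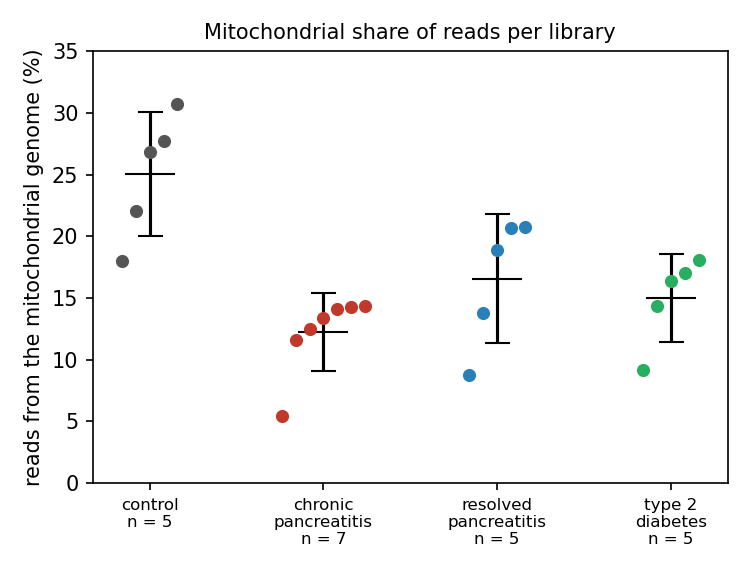
Share of reads from the mitochondrial genome (y axis, percent) in each library (points) of the 4 groups (x axis), with the mean (wide bar) and SD (error bar). The 7 CP libraries lie at 5.46% to 14.4% and the 5 controls at 18.02% to 30.8%.

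The 13 mitochondrially encoded genes fell as a list in CP (camera adjusted p = 6.36e-27 at the preset correlation; adjusted p = 0.0716 with an estimated correlation; fry adjusted p = 0.0125). None of them fell over all genes tested and 13 of 13 fell adjusted over the list alone. MT-ND1, a subunit of respiratory complex I, changed by -1.60 ± 0.37 (log2, SE), from 18835 ± 6178 FPKM in controls to 6458 ± 2348 in CP. MT-CO3 of complex IV changed by -1.23 ± 0.29 and MT-CYB of complex III by -1.52 ± 0.36 (limma adjusted p = 0.396 each). Nuclear copies of mitochondrial genes can share these reads. The 10 most abundant genes of a library took 12.5 ± 1.54% of reads in CP and 23.2 ± 4.70% in controls (exact permutation p = 0.00126, adjusted p = 0.00758).

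The extracellular matrix list rose in CP (camera adjusted p = 1.43e-15; adjusted p = 0.113 with an estimated correlation). All 24 members had positive changes, and 7 rose adjusted over the list alone against 0 over all genes. CTHRC1, a secreted protein of activated fibroblasts, changed by 1.41 ± 0.41, the fibronectin gene FN1 by 1.00 ± 0.32 and the collagen gene COL1A2 by 1.26 ± 0.42 (limma adjusted p = 0.677 for CTHRC1 and 0.756 for FN1 and COL1A2). COL1A1 and COL3A1 had changes of 1.95 ± 0.67 and 1.46 ± 0.58 (adjusted p = 0.779 and 0.886), and COL1A1 ranged from 23.4 to 912 FPKM among CP libraries. Without CP 2, which held the highest matrix score, that score differed by 0.67 (exact permutation p = 0.0130).

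Macrophage genes rose as a list (adjusted p = 2.00e-08; adjusted p = 0.330 with an estimated correlation), with positive changes in 15 of 15 members and 0 called over all genes or adjusted over the list alone. The scavenger receptor gene MSR1 changed by 1.03 ± 0.34 and the mannose receptor gene MRC1 by 0.98 ± 0.39. The cell cycle list rose (median 0.64, 18 of 18 members positive, adjusted p = 7.01e-07; adjusted p = 0.665 with an estimated correlation), and CCNA2, a cyclin of S phase and G2, changed by 0.99 ± 0.36. The adipocyte list fell (20 of 20 members negative, adjusted p = 3.41e-05; adjusted p = 0.667 with an estimated correlation). CIDEA, a lipid droplet protein, changed by -1.51 ± 0.76, and AQP7, a glycerol channel, by -1.16 ± 0.60. No member of the cell cycle or adipocyte lists was called over all genes or adjusted over the list alone. The adipocyte call was lost when CP 2, HP 5, T2D 1 and CTRL 5 were left out together (adjusted p = 0.403, over a range of 2.44e-09 to 0.403 among the 27 alternatives that keep the list test). For macrophages, cell cycle and adipocytes the differences of the score were 0.74, 0.60 and -0.72, and the exact permutation p-values were 0.0631, 0.239 and 0.350 (adjusted p = 0.687, 0.875 and 0.940). Single CP libraries weigh on such differences. The cell cycle scores ran from 0.80 to 3.38 in CP and 0.74 to 1.57 in controls, and the adipocyte scores from 3.61 to 7.37 and 5.03 to 7.59.

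Lists that can respond to tissue handling or RNA quality, though not to these alone, also passed in CP at the preset correlation. Heat shock and unfolded protein response genes rose (median 0.26, 14 of 16 positive, adjusted p = 0.00400; adjusted p = 0.665 with an estimated correlation), a call lost without CP 6 (0.0775), with the chaperone genes PDIA4 at 0.91 ± 0.36 and HSPA5 at 0.57 ± 0.31. Immediate early genes rose (median 0.58, 16 of 19 positive, adjusted p = 0.0142; adjusted p = 0.766 with an estimated correlation), with EGR3 at 1.36 ± 0.61 and EGR2 at 1.20 ± 0.57. That call was lost without CTRL 2 (0.178), CTRL 3 (0.0527), CTRL 4 (0.175), CP 4 (0.146), CP 5 (0.0506) or CP 6 (0.129). Ribosomal protein genes fell (median -0.16, 28 of 32 negative, adjusted p = 0.00618; adjusted p = 0.766 with an estimated correlation), a call lost without CTRL 5 (0.798, direction turned), CP 3 (0.218) or CP 4 (0.146). No member of these 3 lists was called over all genes or adjusted over the list alone.

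The 10 protein-coding genes with the smallest p in CP included MT-ND1, MT-CO3, MT-CYB and MT-ATP6. None passed the threshold (limma adjusted p = 0.396 each). RGS5, a regulator of G protein signalling found in pericytes, stood at 29.7 ± 11.8 FPKM in CP and 80.0 ± 27.6 in controls (log2 change -1.44 ± 0.31), with 7 of 7 CP libraries below the lowest control. OLFML2B, which encodes a secreted glycoprotein, stood at 25.98 ± 22.8 against 5.54 ± 1.37 FPKM (1.79 ± 0.40), and SNAP25, a protein of synaptic vesicle fusion, at 1.64 ± 0.91 against 0.231 ± 0.0746 FPKM (1.03 ± 0.23). All 7 CP libraries were above the highest control for both genes. SPESP1 changed by 0.90 ± 0.21, the ephrin receptor gene EPHA4 by -0.79 ± 0.19 and VIPR1, a receptor of vasoactive intestinal peptide, by -1.44 ± 0.35.

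One gene of 15502 changed in CP, the microRNA gene MIR3163, which lies outside the naming rule and was chosen after its values were seen. MIR3163 (ENSG00000266423) lies on chromosome 11 at 66934434 to 66934506 of hg38, minus strand. It falls in an intron of PC, the pyruvate carboxylase gene, on the same strand, with 0 of its 73 bases in PC exons. PC, also outside that rule and chosen after its values were seen, stood at 28.4 ± 20.1 FPKM in controls (SD, n = 5), 15.9 ± 12.4 in CP (n = 7), 18.96 ± 16.3 in HP (n = 5) and 19.7 ± 8.25 in T2D (n = 5), and did not pass (limma adjusted p = 1.00 in CP and HP). Reads of unspliced PC RNA cannot be separated here from those of MIR3163. MIR3163 had 49 reads in all over the 5 controls (6 to 16 each), 2 over 7 CP, 4 over 5 HP and 7 over 5 T2D libraries. Its change was -1.65 ± 0.23 in CP (limma adjusted p = 0.00476) and -1.54 ± 0.24 in HP (adjusted p = 0.0418). The call in CP was lost with a pseudocount of 0.1 and without CP 2, HP 5, T2D 1 and CTRL 5 together (adjusted p = 0.392 and 0.0796, over a range of 0.000909 to 0.392 among 25 alternatives). A gene with so few reads is not measured precisely at this depth.

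In CP against controls, 809 genes had an unadjusted p under 0.05 where 775.1 are given by chance. Of 43 lists, 19 passed the threshold, 11 up and 8 down, and 0 passed with an estimated correlation. Left out 1 library at a time, the mitochondrial, matrix, macrophage, cell cycle and adipocyte lists kept their calls and the other 14 lists lost them at least once. Without CP 4 the count was 9. Those 14 had adjusted p-values of 0.665 to 0.766 with an estimated correlation, and they included blood endothelium (median -0.32, adjusted p = 0.121 without CTRL 1), adipose progenitors and fibroblasts (median 0.35, 2 members, SFRP2 and LUM, rose adjusted over the list alone, adjusted p = 0.489 without CTRL 1) and lipid-associated macrophages (median 0.31, 3 members, CTSB, GPNMB and CHI3L1, rose adjusted over the list alone, adjusted p = 0.146 without CP 4).

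**Figure D2:**
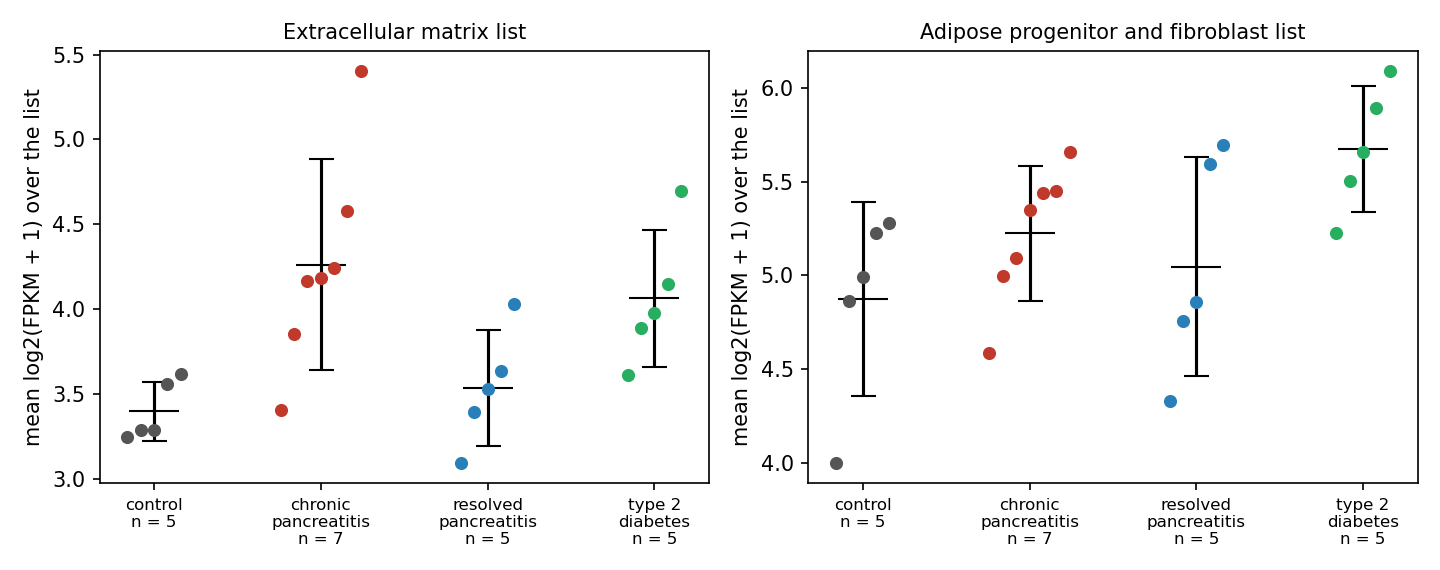
Scores of the extracellular matrix list (left) and the adipose progenitor and fibroblast list (right), each the mean of log2(FPKM + 1) over the list's members (y axis), per library (points) in the 4 groups (x axis), with the mean (wide bar) and SD (error bar). The matrix score was 3.40 ± 0.17 in controls, 4.26 ± 0.62 in CP, 3.53 ± 0.34 in HP and 4.06 ± 0.40 in T2D.

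Tissue labelled as resolved pancreatitis was compared with controls to see whether the differences of CP are also found there. In HP, mitochondrially encoded genes were lower and T cell genes higher as lists at the preset correlation between genes only (adjusted p = 0.956 each with an estimated correlation). The mitochondrial share of reads was 16.6 ± 5.20% (SD, n = 5) against 25.1 ± 5.04% in controls (n = 5), a difference with an exact permutation p of 0.0397 that did not pass after adjustment (adjusted p = 0.0794 over 12 tests). With 1 library left out of this test alone, the adjusted p ranged from 0.0317 to 0.140. It was 0.0317 without CTRL 3 (exact permutation p = 0.00794), 0.127 without CTRL 5, and 0.140 without CTRL 1, CTRL 2, CTRL 4, HP 1 or HP 2. The 16 T cell genes had a median log2 change of 0.73, and CD3E, a chain of the T cell receptor complex, stood at 12.5 ± 16.8 FPKM in HP and 4.54 ± 4.80 in controls.

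The mitochondrially encoded list fell in HP (median -0.78, 13 of 13 members negative, camera adjusted p = 3.21e-12; adjusted p = 0.956 with an estimated correlation) and kept its call without any 1 library. MT-CO1 of complex IV changed by -0.99 ± 0.32 and MT-CO3 by -0.85 ± 0.31, and no member was called over all genes or adjusted over the list alone. The mitochondrial score was lower by -0.77, with 2 of 5 HP libraries below the lowest control (exact permutation p = 0.0317, adjusted p = 0.570).

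The T cell list rose in HP (15 of 16 members positive, adjusted p = 1.36e-06; adjusted p = 0.956 with an estimated correlation), with CD8A at 0.80 ± 0.37 and CD2 at 0.99 ± 0.55. Without HP 5 the adjusted p was 0.166. The T cell score differed by 0.73 (exact permutation p = 0.206, adjusted p = 0.848) and by 0.29 without HP 5 (exact permutation p = 0.460). Lymphoid chemokines and receptors rose as a list (median 0.66, 9 of 9 positive, adjusted p = 0.00425; adjusted p = 0.956 with an estimated correlation). Their adjusted p was 0.455 without HP 5, and CXCL12, which retains lymphocytes and progenitors in tissue, changed by 0.81 ± 0.42 and CD40LG by 0.66 ± 0.43. The B cell gene MS4A1 ranged from 0.332 to 132 FPKM in HP and from 0.164 to 16.9 in controls. The cytotoxic and NK cell list rose (median 0.51, 11 of 13 positive, adjusted p = 0.00425; adjusted p = 0.956 with an estimated correlation), although the member with the smallest p, FGFBP2, was lower by -1.31 ± 0.56, beside GZMK at 0.57 ± 0.30. That call was lost without HP 1 (adjusted p = 0.113) or CTRL 3 (0.0778). No member of these 3 lists was called over all genes or adjusted over the list alone.

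**Figure D3:**
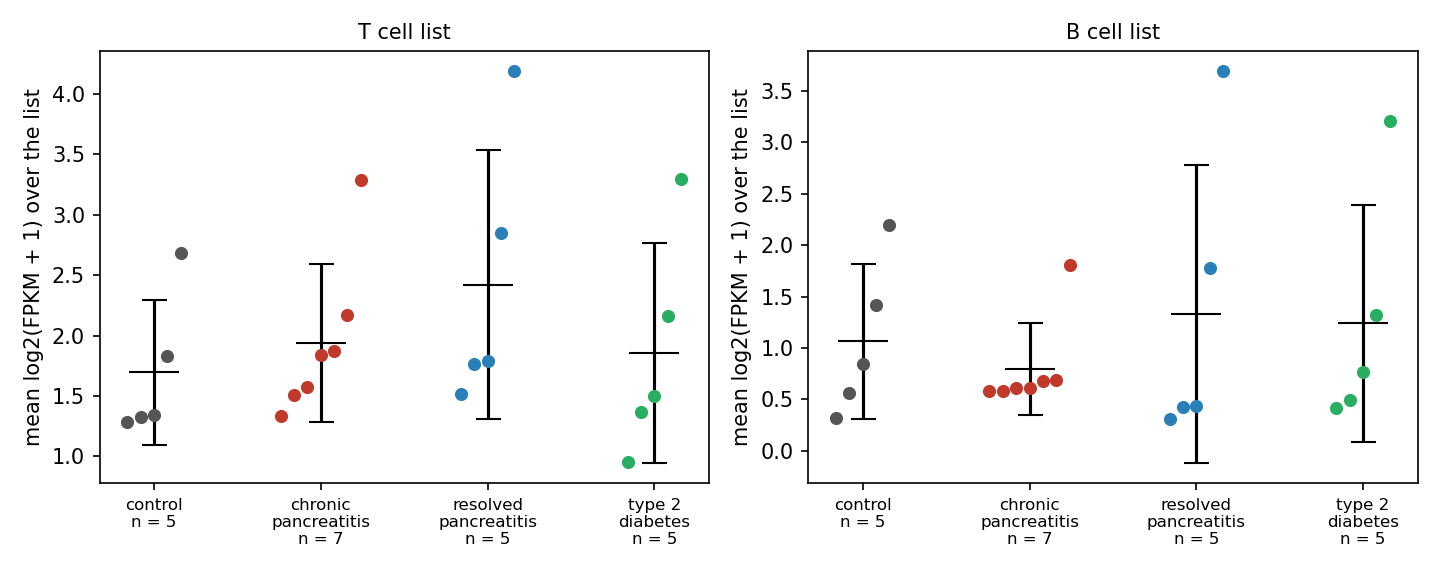
Scores of the T cell list (left) and the B cell list (right), each the mean of log2(FPKM + 1) over the list's members (y axis), per library (points) in the 4 groups (x axis), with the mean (wide bar) and SD (error bar). Single libraries stand above the rest of their group, among them HP 5 with a T cell score of 4.19.

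Blood endothelium genes fell in HP (median -0.28, 13 of 15 negative, adjusted p = 0.00425; adjusted p = 0.962 with an estimated correlation), a call lost without CTRL 1 (0.444) or HP 5 (0.278). PECAM1 and KDR had log2 changes of -0.42 ± 0.23 and -0.39 ± 0.26. Mast cell genes rose (median 0.52, 7 of 9 positive, adjusted p = 0.00667; adjusted p = 0.956 with an estimated correlation), a call lost without HP 1 (0.123). HPGDS, a prostaglandin D synthase, had a log2 change of 1.14 ± 0.44 and the carboxypeptidase gene CPA3 of 0.97 ± 0.51. Adipocyte genes fell (median -0.49, 19 of 20 negative, adjusted p = 0.00510; adjusted p = 0.962 with an estimated correlation), a call lost without CTRL 3 (0.0778), CTRL 5 (0.305) or HP 5 (0.789). CIDEA and AQP7 had changes of -1.19 ± 0.82 and -0.80 ± 0.65. No member of the blood endothelium, mast cell or adipocyte lists was called in HP over all genes or adjusted over the list alone.

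Lists that can respond to tissue handling, though not to it alone, passed in HP as well. Heat shock and unfolded protein response genes rose (median 0.22, 15 of 16 positive, adjusted p = 0.00425; adjusted p = 0.956 with an estimated correlation), a call lost without HP 2 (0.104), with SDF2L1 at 0.80 ± 0.38 and HSPA5 at 0.55 ± 0.33. Immediate early genes rose (median 0.54, 16 of 19 positive, adjusted p = 0.0224; adjusted p = 0.962 with an estimated correlation), with EGR2 at 1.63 ± 0.62, EGR3 at 1.43 ± 0.66 and KLF6 at -0.75 ± 0.35. That call was lost without CTRL 2 (0.204), CTRL 3 (0.0778), CTRL 4 (0.239), HP 2 (0.903) or HP 4 (0.221). No member of these 2 lists was called over all genes or adjusted over the list alone.

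Among single genes in HP, MIR3163 was the 1 gene past the threshold of 15502, and its call was lost without any of 8 of the 10 libraries (highest adjusted p 0.268, without CTRL 3), all but CTRL 1 and HP 4. The protein-coding gene with the smallest p was CHKA, which encodes choline kinase alpha, at 5.77 ± 1.76 FPKM in HP and 11.7 ± 2.59 in controls (log2 change -0.92 ± 0.19, limma adjusted p = 0.578). HSD17B11, a lipid droplet dehydrogenase, stood at 19.4 ± 2.63 against 34.5 ± 7.75 FPKM (-0.78 ± 0.19), GNAO1 at 1.21 ± 0.469 against 0.369 ± 0.178 (0.67 ± 0.17), and CA3, a carbonic anhydrase, at 4.80 ± 3.37 against 1.09 ± 1.05 (1.42 ± 0.43). SCARA3 changed by 1.30 ± 0.37, with 5 of 5 HP libraries above the highest control, and the ion channel gene MCOLN3 by -1.37 ± 0.36. LONRF1, ST3GAL6, EFHD1 and MDM2 had changes of -1.02 ± 0.30, -0.68 ± 0.20, -1.27 ± 0.38 and -0.59 ± 0.18.

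In HP, 409 genes had an unadjusted p under 0.05 (775.1 by chance). Of 43 lists, 11 passed, 6 up and 5 down, and 0 passed with an estimated correlation (adjusted p = 0.956 to 0.962 for the 11). Left out 1 library at a time, the mitochondrial list kept its call and the other 10 lost theirs at least once. The count was 7 without CTRL 3 and 17 without HP 2 or HP 4.

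Adipose tissue of donors with type 2 diabetes was compared with controls as the setting of metabolic disease in the same depot. In T2D, mitochondrially encoded and blood endothelium genes were lower, and matrix, progenitor, mast cell and immediate early genes higher, as lists at the preset correlation between genes only. With an estimated correlation none of these 6 lists passed (adjusted p = 0.177, 0.177, 0.177, 0.146, 0.366 and 0.509). The mitochondrial share of reads was 15.01 ± 3.53% (SD, n = 5) against 25.1 ± 5.04% in controls (exact permutation p = 0.0159, adjusted p = 0.0476 over 12 tests). Those 12 tests include the share of the 10 most abundant genes, which gave the same exact permutation p of 0.0159 in T2D. These shares move together, so the pass in T2D depends on which tests are counted. With 1 library left out of the test of the mitochondrial share alone, the adjusted p was 0.0714 without T2D 2, T2D 3, T2D 4 or T2D 5 (exact permutation p = 0.0238 each). It was 0.0317 without CTRL 3 (exact permutation p = 0.00794). The progenitor and fibroblast score was higher by 0.80 and the matrix score by 0.67 (exact permutation p = 0.0159 each, adjusted p = 0.417 each), with 4 of 5 T2D libraries above the highest control for both. The mast cell score was higher by 0.61, with 5 of 5 above (exact permutation p = 0.00794, adjusted p = 0.417). ADIPOQ and PLIN1 differed by 0.32 ± 0.85 and 0.16 ± 0.71, within the spread between libraries.

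The mitochondrially encoded list fell in T2D (median -0.89, 13 of 13 negative, camera adjusted p = 2.88e-13; adjusted p = 0.177 with an estimated correlation), and 10 of 13 members fell adjusted over the list alone against 0 over all genes. MT-CYB changed by -1.11 ± 0.39 and MT-ND3 by -1.05 ± 0.37. Blood endothelium genes fell (median -0.70, 15 of 15 negative, adjusted p = 1.14e-09; adjusted p = 0.177 with an estimated correlation), with 0 members called adjusted over the list alone or over all genes. KDR, a receptor of vascular endothelial growth factor, changed by -0.79 ± 0.26, and the angiopoietin receptor gene TEK by -0.70 ± 0.26.

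The matrix list rose in T2D (median 0.64, 22 of 24 positive, adjusted p = 1.53e-09; adjusted p = 0.177 with an estimated correlation), and 2 members rose adjusted over the list alone, LOXL1, a collagen crosslinking enzyme (1.08 ± 0.30), and THBS2, a thrombospondin (1.63 ± 0.48), with 0 over all genes. Progenitor and fibroblast genes rose (median 0.69, 14 of 16 positive, adjusted p = 4.19e-07; adjusted p = 0.146 with an estimated correlation). LUM (1.47 ± 0.48), FBLN1 (1.31 ± 0.45) and SFRP2 (1.94 ± 0.67) were the 3 members that rose adjusted over the list alone, with 0 over all genes. TGF-beta response genes rose (median 0.42, 12 of 14 positive, adjusted p = 4.06e-05; adjusted p = 0.146 with an estimated correlation), with BAMBI (0.82 ± 0.23) and LTBP2 (1.44 ± 0.46) past the threshold adjusted over the list alone and 0 members over all genes. Matrix proteases and inhibitors rose (median 0.72, 12 of 13 positive, adjusted p = 3.50e-05; adjusted p = 0.177 with an estimated correlation), with TIMP2, an inhibitor of matrix metalloproteinases, past the threshold adjusted over the list alone (0.73 ± 0.19, 0 members over all genes) and MMP2 at 1.21 ± 0.50.

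Mast cell genes rose in T2D (median 0.76, 8 of 9 positive, adjusted p = 0.000358; adjusted p = 0.366 with an estimated correlation), with CPA3 at 1.21 ± 0.51 and HPGDS at 1.01 ± 0.44. Immediate early genes, which respond within minutes to stimulation and to tissue handling, rose (median 1.20, 19 of 19 positive, adjusted p = 4.19e-07; adjusted p = 0.509 with an estimated correlation), with EGR3 at 1.61 ± 0.66 and IER3 at 1.40 ± 0.63. No member of these 2 lists was called over all genes or adjusted over the list alone, and the immediate early score differed by 1.01 (exact permutation p = 0.119, adjusted p = 0.730). Ribosomal protein genes fell (median -0.25, 32 of 32 negative, adjusted p = 2.37e-06; adjusted p = 0.738 with an estimated correlation), a call lost without CTRL 5 (0.144), with 0 members called over all genes or adjusted over the list alone.

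No gene of 15502 passed the threshold in T2D with limma, where 642 had an unadjusted p under 0.05 (775.1 by chance). Limma-voom on the recovered reads also called 0, library weights called 1, and 1 was called without T2D 5. CCDC80, a secreted matrix protein, had the smallest p among protein-coding genes, at 73.2 ± 10.4 FPKM in T2D and 20.2 ± 8.34 in controls (log2 change 1.90 ± 0.41, limma adjusted p = 0.590). FANCE, of the Fanconi anaemia DNA repair pathway, stood at 1.49 ± 0.295 against 2.96 ± 0.301 FPKM (-0.67 ± 0.15), and TIMP2 at 121 ± 12.9 against 72.7 ± 10.6. For all 3 genes the 5 T2D libraries lay outside the range of the controls. IL10, an anti-inflammatory cytokine, was at 12.4 ± 8.70 against 2.03 ± 0.748 FPKM (1.84 ± 0.50), and the matrix genes MFAP2 and EFEMP1 changed by 1.18 ± 0.31 and 1.37 ± 0.37. SCARA3, SEMA3C, SAMD11 and HDHD5 had changes of 1.42 ± 0.37, 1.45 ± 0.38, 1.04 ± 0.26 and -0.56 ± 0.13.

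Of 43 lists in T2D, 17 passed the threshold, 12 up and 5 down, and 0 passed with an estimated correlation. The lists described other than ribosomal proteins, 8 in number, kept their calls when any 1 library was left out. The other 9 lost theirs at least once, with adjusted p-values of 0.509 to 0.771 with an estimated correlation.

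Chronic was compared directly with resolved pancreatitis, which also tests whether the 2 groups differ in their distance from controls. Matrix, macrophage and lipid-associated macrophage genes were higher in CP than in HP, and MHC class II, ribosomal protein and mitochondrially encoded genes lower, as lists at the preset correlation between genes only. With an estimated correlation none of these 6 lists passed (adjusted p = 0.235, 0.411, 0.334, 0.620, 0.651 and 0.466). The matrix score was higher in CP by 0.73, with 5 of 7 CP libraries above the highest HP library (exact permutation p = 0.0341, adjusted p = 0.570), and the TGF-beta response score by 0.39, with 6 of 7 above (exact permutation p = 0.0152, adjusted p = 0.417). The mitochondrial share of reads differed by -4.34 percentage points (exact permutation p = 0.0934, adjusted p = 0.140). With 1 library left out of this test alone, the adjusted p ranged from 0.0381 to 0.275. It was 0.0381 without HP 2 (exact permutation p = 0.0121), 0.222 without HP 4, and 0.275 without HP 3 or HP 5. The 0.0381 rests also on p-values of other comparisons, kept from all libraries.

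The matrix list rose in CP against HP (median 0.81, 23 of 24 positive, camera adjusted p = 4.24e-15; adjusted p = 0.235 with an estimated correlation), and FN1 (1.20 ± 0.32) and COL5A2 (1.03 ± 0.30) were the 2 members past the threshold adjusted over the list alone, with 0 over all genes. Macrophage genes rose (median 0.59, 14 of 15 positive, adjusted p = 5.36e-07; adjusted p = 0.411 with an estimated correlation), with MSR1 at 1.09 ± 0.34 and the Fc receptor gene FCGR3A, which has a close paralog and is uncertain, at 1.17 ± 0.46. Lipid-associated macrophage genes rose (median 0.39, 13 of 15 positive, adjusted p = 6.49e-05; adjusted p = 0.334 with an estimated correlation). The lysosomal genes CTSB (1.09 ± 0.30) and LIPA (0.67 ± 0.22) were its 2 members past the threshold adjusted over the list alone, with 0 over all genes. TGF-beta response genes rose (median 0.19, 11 of 14 positive, adjusted p = 0.00154; adjusted p = 0.390 with an estimated correlation), with LTBP2 at 0.98 ± 0.43.

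MHC class II genes fell in CP against HP (median -0.65, 12 of 14 negative, adjusted p = 6.49e-05; adjusted p = 0.620 with an estimated correlation), with HLA-DOA at -1.22 ± 0.39 and CIITA, the transactivator of these genes, at -0.76 ± 0.30. The mitochondrially encoded list fell (median -0.62, 13 of 13 negative, adjusted p = 3.19e-07; adjusted p = 0.466 with an estimated correlation), with MT-ND3 at -0.82 ± 0.34 and MT-ND1 at -0.75 ± 0.37, and its adjusted p was 0.0509 without a filter on low values. Ribosomal protein genes fell (median -0.25, 30 of 32 negative, adjusted p = 5.36e-07; adjusted p = 0.651 with an estimated correlation), with RPL30 at -0.42 ± 0.19 and RPS23 at -0.39 ± 0.19, which have many processed pseudogenes and are uncertain. T cell genes fell (median -0.57, 14 of 16 negative, adjusted p = 0.00101; adjusted p = 0.668 with an estimated correlation), a call lost without HP 5 (0.846), with CD8A at -0.54 ± 0.34 and CD3G at -0.59 ± 0.41. No member of these 4 lists or of the macrophage and TGF-beta lists was called over all genes or adjusted over the list alone.

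No gene of 15502 passed the threshold between CP and HP with limma, where 483 had an unadjusted p under 0.05 (775.1 by chance), and limma-voom on the recovered reads also called 0. HSPA2, a heat shock protein of the HSP70 family, had the smallest p, at 3.46 ± 0.545 FPKM in CP and 1.52 ± 0.355 in HP (log2 change 0.82 ± 0.18, limma adjusted p = 0.999), with 7 of 7 CP libraries above the highest HP library. RGS5 stood at 29.7 ± 11.8 against 80.2 ± 38.1 FPKM (-1.40 ± 0.31), with 7 of 7 below. TMIGD3, GPR137B, CTSB, NPL and HAVCR2 had changes of 1.71 ± 0.41, 0.86 ± 0.22, 1.09 ± 0.30, 1.09 ± 0.30 and 0.85 ± 0.24. SPESP1 changed by 0.75 ± 0.21 and HIST1H2BC, a histone gene with near-identical copies that is uncertain, by 0.90 ± 0.22.

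Of 43 lists between CP and HP, 19 passed the threshold, 10 up and 9 down, and 0 passed with an estimated correlation (adjusted p = 0.235 to 0.701 for the 19). Left out 1 library at a time, 10 lists kept their calls and 9 lost theirs at least once. The 3 other lists that kept them were complement (median 0.44; adjusted p = 0.466 with an estimated correlation), matrix proteases and inhibitors (median 0.28; adjusted p = 0.466) and nuclear encoded oxidative phosphorylation (median -0.25; adjusted p = 0.668).

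In the secondary comparisons limma called 0 genes for CP against T2D and 0 for HP against T2D, where 445 and 699 genes had an unadjusted p under 0.05 and limma-voom also called 0. The mean of CP and HP against controls, and the test of any difference among the 4 groups, each called 1 gene, MIR3163 (603 and 553 genes with an unadjusted p under 0.05). The test of any difference called 0 without CTRL 3, CTRL 4, CTRL 5 or CP 5, and the mean of CP and HP called 2 without CP 4. The lists past the threshold numbered 16 for CP against T2D (10 without CP 3), 20 for HP against T2D and 16 for the mean of CP and HP against controls, and 0 of them passed with an estimated correlation. In HP against T2D, all 32 ribosomal protein genes were positive (median 0.35, adjusted p = 1.77e-09; adjusted p = 0.524 with an estimated correlation) and 23 of 24 matrix genes negative (median -0.54, adjusted p = 5.88e-07; adjusted p = 0.424 with an estimated correlation).

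Because the comparisons share the 5 control libraries, their fold changes are correlated with no effect at all. Across 15502 genes, which are not independent replicates, the log2 changes of CP and HP against controls had a correlation of 0.589, where unchanged groups simulated against the same controls gave 0.539 on average and 0.564 at most in 100 simulations. The simulated noise was drawn independently for each gene, while real genes vary together. The simulated range is therefore too narrow to test whether CP and HP share changes. The covariance exceeded the simulated one by 0.000262, and with the controls split between the 2 comparisons the median correlation was 0.0375 (range -0.175 to 0.200 over 20 splits). For CP and T2D the correlation was 0.631 against a simulated 0.538, the covariance differed by 0.00797 and the split controls gave 0.0729. For HP and T2D it was 0.436 against 0.501, with -0.0125 and -0.0565. MIR3163 was the 1 gene that fell in both CP and HP, 2 comparisons that use the same 5 controls.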

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

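The screening of libraries, the scores of pathway lists, the score tests against T2D and the adjustment over 138 differences were chosen after the list scores and named genes had been seen, while the cell type scores of CP against HP were planned.

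In each group of 5 or 7 libraries, the gap between the highest or lowest library and its nearest neighbour was set against the range of the group. Of 390 such groups of list scores, read numbers, mitochondrial shares and named genes, 35 had a gap above Dixon's 95% critical value, where chance gives about 1 in 20, or 19.5. That share holds for independent, normally distributed values. Many of these items overlap, such as the mitochondrial list, its genes and the share of reads. A gene with reads in a single library of a group, as MIR3163 and INS had, passes by construction. The 35 therefore do not show an excess over chance. The gap as a share of the range is given in brackets, and the cause was not tested for any of these libraries.

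In CP, CP 2 was the highest library for B cells (0.918), plasma cells (0.687) and T cells (0.572). It was the lowest for the mitochondrially encoded list (0.791), the mitochondrial share of reads (0.691), MT-CYB (0.753) and MT-ATP6 (0.766). CP 1 was the highest for mesothelium (0.595), KRT19 (0.589) and SCARA3 (0.591), CP 6 for Schwann cells and nerve (0.749), and CP 7 for MIR3163 (1) and INS (1), which had 0 reads in the other 6.

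In HP, HP 2 was the highest library for ductal epithelium (0.791), mesothelium (0.776) and KRT19 (0.901). HP 3 was the highest for acinar cells (0.790) and SPESP1 (0.712), and HP 4 for MIR3163 (1), with 0 reads in the other 4. HP 4 was the lowest for islet endocrine cells (0.751) and HP 5 for SEMA3C (0.734).

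In T2D, T2D 2 was the highest library for ductal epithelium (0.816) and the lowest for MT-ATP6 (0.826). T2D 1 was the highest for mast cells (0.779) and lymphoid chemokines (0.711), and T2D 4 the lowest for CPA1 (0.778).

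Among controls, CTRL 5 was the highest library for matrix proteases and inhibitors (0.809), inflammatory cytokines and chemokines (0.819) and senescence (0.768). CTRL 2 was the highest for mast cells (0.774) and mesothelium (0.802), and CTRL 1 for angiogenesis (0.747) and INS (1, with 0 reads in the other 4). CTRL 1 was the lowest for ductal epithelium (0.871) and CTRL 3 for the mitochondrially encoded list (0.763).

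List scores were also compared directly between patient groups, which share their controls, with exact two-sided permutation tests. Of 138 differences, 5 had an unadjusted p under 0.05, and all 5 had an adjusted p of 0.914 over the 138. Over the 184 score tests of the 4 main comparisons, the 3 of CP against HP had an adjusted p of 0.5679 (islet endocrine), 0.570 (matrix) and 0.417 (TGF-beta). Scores were higher in CP than in HP for islet endocrine cells (by 0.125, exact p = 0.0278), the extracellular matrix list (by 0.726, exact p = 0.0341) and TGF-beta response (0.394, exact p = 0.0152). HP against T2D differed by -0.342 for ductal epithelium (exact p = 0.0397) and by -0.550 for TGF-beta response (exact p = 0.0317). The ductal difference leans on T2D 2, with a score of 1.74 against a mean of 0.970 in the other T2D libraries and 0.782 in HP. HP 2 works the other way, at 1.11 against 0.699 in the other HP libraries.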

How the results depend on the processing

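Limma-voom on the recovered reads, the filter of at least 100 recovered reads and leaving out CP 2, HP 5, T2D 1 and CTRL 5 together, picked because they stood farthest apart on the fibrosis and lymphocyte lists, were chosen after the results had been seen.

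The counts of changed genes were 1 for CP, 1 for HP and 0 for T2D against controls, 0 for CP against HP, CP against T2D and HP against T2D, and 1 for the mean of CP and HP and for any difference among the 4 groups. The counts of 1 all became 0 with a pseudocount of 0.1, with FPKM of at least 5 in at least 5 libraries, with protein-coding genes only, with at least 100 recovered reads, and without the 4 libraries. HP was also 0 with upper-quartile scaling, no filter, only the 2 groups in the fit, limma-voom and the replicate number as a block, and any difference among the 4 groups was 0 with limma-voom and the block. The block gave 1 for CP against T2D and 1 for HP against T2D, and library weights gave 2 for HP and 1 for T2D.

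The lists past the threshold fell to 0 in all 7 comparisons with an estimated correlation, and with fry to 1 for CP against controls, 1 for the mean of CP and HP, and 0 for the other 5. CP against HP gave 11 of 35 lists with FPKM of at least 5, and the mean of CP and HP gave 9 with the acinar score as covariate.

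Without 1 library at a time, changed genes ranged over 1 to 1 for CP, 0 to 1 for HP, 0 to 1 for T2D, 1 to 2 for the mean, 0 to 1 for any difference, and 0 to 0 for the 3 comparisons of patient groups. Lists ranged over 9 to 22 for CP, 7 to 17 for HP, 12 to 19 for T2D, 13 to 25 for CP against HP, 10 to 17 for CP against T2D, 14 to 24 for HP against T2D and 11 to 22 for the mean. Score tests past the threshold stayed at 0, which the design nearly fixes. With all libraries, the smallest exact permutation p is 0.00126 for 7 against 5 libraries and 0.00794 for 5 against 5. At 0.00126, the mitochondrial score in CP still had an adjusted p of 0.232 over the 184 tests. The count of 0 therefore says little about stability. The correlation of CP and HP changes ranged over 0.491 to 0.679.

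The direction of a list turned 8 times, never past the threshold then (in brackets the adjusted p, with its range without 1 library at a time): glucocorticoid response in T2D without CTRL 1 (0.940, range 0.00135 to 0.940), ribosomal proteins in CP without CTRL 5 (0.798, range 4.3e-05 to 0.798), B cells in CP against HP without HP 5 (0.827, range 0.000117 to 0.827) and mesothelium in T2D without T2D 2 (0.773, range 0.000488 to 0.773). Without the 4 libraries they were oxidative phosphorylation (0.272) and ribosomal proteins (0.848) in CP, and adipocyte identity (0.615) and lipid storage (0.617) in HP.

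Of the values of lists and single genes, 10076 stayed on the same side of the threshold, 340 were no longer past it and 1 newly passed. Of these, single genes made 8575 values, of which 8557 stayed on the same side and 17 were no longer past it. MIR3163 was the 1 named gene past the threshold, and all 17 were its values. Nearly all the values that stayed belong to genes that had not passed and had no call to lose. They do not measure how stable a call is. Negative binomial count models were not run, and the added fold limit was run for genes only.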

Other observations

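Planned were the list tests, the scores of cell type lists and the counts over other splits of the samples, and the nuclear retained RNA score was chosen before its result was seen; all other tests of this part, the use of cell type scores against an explanation, and the principal components of the splits were chosen after the results had been seen, and the bound for T cells was tightened after its value was known.

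The mitochondrial share of reads was lower in CP and T2D than in controls (exact permutation tests, adjusted p = 0.00758 and 0.0476). In T2D the adjusted p was 0.0714 without T2D 2, T2D 3, T2D 4 or T2D 5. In HP the share was lower as well, at 16.6% against 25.1%, and did not pass (exact permutation p = 0.0397, adjusted p = 0.0794). These comparisons use the same 5 controls, so they are not independent of each other. The mitochondrially encoded list was lower in CP, T2D and HP at the preset correlation (adjusted p = 0.0716, 0.177 and 0.956 with an estimated correlation). Adjusted for the adipocyte score by the slope within groups, the mitochondrial score still differed by -1.26 ± 0.27 in CP (SE), against -1.36 unadjusted. The exact permutation p was 0.00126 for both, the smallest the design can give. Along that slope, the adipocyte score accounted for little of the difference in CP. The adipocyte score itself differed by -0.72 ± 0.70 there (exact permutation p = 0.350), and the error of the slope is not in the ± 0.27. Fewer adipocytes are therefore not excluded as a cause in CP. In T2D the adjusted difference was -0.91 ± 0.28 (unadjusted -0.92, exact permutation p = 0.0238). The adipocyte score itself differed by only -0.04 ± 0.48 in T2D, so the adjustment could hardly move that value and decides nothing there. Over all 184 score tests the differences before this adjustment had an adjusted p of 0.232 and 0.548. In CP, the score of nuclear encoded oxidative phosphorylation genes differed by -0.14 ± 0.26, against an equal fall from both genomes. That list was itself called lower in CP and in T2D at the preset correlation. The call was lost in 9 of 27 alternatives in CP and 4 of 25 in T2D, so a smaller fall of the nuclear encoded genes stays open. The nuclear retained RNA score differed in CP by 0.00991 ± 0.09. Its genes lie outside the naming rule. KCNQ1OT1 and SNHG14 stood at 0.160 and 0.985 FPKM in controls, where log2(FPKM + 1) can hardly move. MALAT1 and NEAT1 stood at 54.9 and 87.3 FPKM in CP against 56.0 and 91.6 in controls. OIP5-AS1 and MEG3 stood at 12.1 and 17.2 against 11.4 and 12.3. These few genes argue against a large rise in the share of nuclear RNA, and a small one stays open. Immediate early genes were higher in CP, HP and T2D at the preset correlation (adjusted p = 0.766, 0.962 and 0.509 with an estimated correlation). At the same preset correlation, heat shock and unfolded protein response genes were higher in CP and HP (0.665 and 0.956 with an estimated one). Ribosomal protein genes were lower in CP and T2D (0.766 and 0.738). No label records tissue handling or the quality of the RNA, so these, differences between donors and the disease itself stay open.

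The extracellular matrix list was higher in CP than in controls at the preset correlation (adjusted p = 0.113 with an estimated correlation). Without CP 2 the score still differed by 0.67 (exact permutation p = 0.0130), against 1 library as the cause. Of 15 other cell type lists with a mean score of at least 1 in controls, 11 were higher in CP, among them macrophages (0.74 ± 0.34) and lymphatic endothelium (0.45 ± 0.36), and 4 were lower, among them blood endothelium (-0.38 ± 0.35) and B cells (-0.27 ± 0.38). Their mean differed by 0.13 ± 0.15, and the matrix score minus that mean by 0.74 ± 0.26 (exact permutation p = 0.0215). A lower share of adipocytes would raise markers of other cells alike. The matrix score minus the blood endothelium score differed by 1.24 ± 0.50 (exact permutation p = 0.0391). Minus the macrophage score it differed by only 0.13 ± 0.32 (exact permutation p = 0.682). Several lists had low scores, where log2(FPKM + 1) understates a rise, and the mean includes red blood cells (-0.69 ± 0.37). The mean therefore cannot decide, and a lower share of adipocytes stays open as the cause. More fibroblasts and more matrix expression per fibroblast cannot be told apart, since the matrix score minus the progenitor and fibroblast score differed by 0.51 ± 0.36 (exact permutation p = 0.222), and the site of sampling and the disease stay open.

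The T cell list was higher in HP than in controls at the preset correlation (adjusted p = 0.956 with an estimated correlation). The red blood cell score differed by -0.76 ± 0.30, against more blood in the HP pieces. Without HP 5 the T cell score differed by 0.29 ± 0.40, against 0.73 ± 0.57 with it. Lymphoid tissue in that piece and more T cells across HP cannot be told apart, since the value without HP 5 is smaller than its own error.

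Random regroupings of the samples into groups of the same sizes were fitted alike, with the real split among the 100. For changed genes, 10 of 100 splits gave as many (real 1, highest other 215) for CP against controls and 10 of 100 (real 1, highest other 16) for the mean of CP and HP, so chance cannot be excluded for these. For T2D against controls, CP against HP, CP against T2D and HP against T2D the real counts were 0 (highest others 4, 2, 4 and 89), which all 100 splits reach by definition, so the splits test nothing there. For HP against controls 4 of 100 splits gave as many (real 1, highest other 19). For any difference among the 4 groups 4 of 100 splits gave as many (real 1, highest other 3). These counts lie under 1 in 20 when each is taken alone. They were not adjusted over the 8 numbers, so chance is not excluded for them either. Both rest on 1 gene and are not stable. The count for HP was 0 without CTRL 2, CTRL 3, CTRL 4, CTRL 5, HP 1, HP 2, HP 3 or HP 5, that for any difference was 0 without CTRL 3, CTRL 4, CTRL 5 or CP 5, and both were 0 with limma-voom on the recovered reads. Splits that called 215 or 89 genes point to a structure of the samples. The split with 215 took 56.2% of the variance of the first principal component (median of the 100 splits 3.26%) and the split with 89 took 79.8% of that of the second (median 5.45%), the largest share of the 100 splits in each case. Over all 22 libraries the first component had an absolute correlation of 0.829 with the adipocyte score and 0.725 with the T cell score, and the groups held 2.79% of it. For the second these were 0.0713, 0.187 and 12.4%. Its absolute correlation with the mitochondrial score was 0.0232, and the scores of the other lists were not set against it.

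For lists past the threshold, as many were given by 27 of 100 (real 19, highest other 27) for CP against controls, 79 of 100 (real 11, highest other 29) for HP, 43 of 100 (real 17, highest other 25) for T2D, 31 of 100 (real 19, highest other 27) for CP against HP, 52 of 100 (real 16, highest other 24) for CP against T2D, 23 of 100 (real 20, highest other 32) for HP against T2D and 46 of 100 (real 16, highest other 30) for the mean of CP and HP. Chance cannot be excluded for any of these 7 numbers of lists.

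RGS5, a pericyte gene, stood at 29.7 ± 11.8 FPKM in CP (SD, n = 7) against 80.0 ± 27.6 in controls, 80.2 ± 38.1 in HP and 57.4 ± 18.1 in T2D (n = 5 each), and fell in CP adjusted over its list alone (limma adjusted p = 0.00187 over the list, 0.396 over all genes). The other 13 members of the smooth muscle and pericyte list did not pass, and those with the next smallest p were CSPG4 (log2 change -0.47 ± 0.48, SE), LMOD1 (-0.38 ± 0.42) and ACTG2 (0.58 ± 1.03). Of the 14 members, 9 had positive and 5 negative changes. The list as a whole did not pass either (camera adjusted p = 0.401). The cause was not tested.

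The islet endocrine score was higher in CP than in controls by 0.15, with 6 of 7 above the highest control (exact permutation p = 0.0126, adjusted p = 0.417). It was also higher in T2D by 0.08, with 2 of 5 above (exact permutation p = 0.0397, adjusted p = 0.608), and differed by 0.02 in HP (exact permutation p = 0.286). None of the 14 members was kept for the gene tests, so the members named here other than INS lie outside the naming rule and were chosen after their values were seen. The hormone genes PPY and IAPP had no reads in any CP or control library. GCG averaged 0.00189 FPKM in CP and 0.0134 in controls, and INS 0.00311 and 0.00938, against the direction of the score. SCG2 and CHGA, secretory granule genes also found in nerve, stood at 2.26 ± 4.19 and 0.215 ± 0.392 FPKM in CP against 0.0775 ± 0.0379 and 0.00888 ± 0.0168 in controls, with the highest CP library at 11.7 FPKM of SCG2. The cause was not tested.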
